A study of Sus scrofa with 2 samples.

How the data were processed

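Single-nucleus RNA sequencing was done on frozen olfactory mucosa of newborn piglets (Sus scrofa), with 1 library from a wild type piglet and 1 from a CFTR knockout piglet. Per the labels' protocols, dissected tissue was frozen, sectioned in a cryostat, ground in a citric acid buffer and filtered, and the nuclei were captured in droplets with 10x Genomics chemistry. Each droplet carries a barcode and each captured transcript a unique molecular identifier (UMI), so that a transcript is counted once. The deposited values are whole-number UMI counts per gene and nucleus, not normalized, in a table per library. The submitters' processing notes list Cell Ranger, Seurat 4.0 and R 4.0.2 with no role or order. The aligner, the genome build, the annotation, the chemistry version and the part of each transcript that was counted are not given in the sources used here. No barcode in the deposited tables had fewer than 500 UMIs.

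The table of the wild type library held 4715 barcodes with 18731495 UMIs (median 3032 per nucleus), and that of the knockout library 6054 barcodes with 16623086 UMIs (median 2138). Both listed 25880 genes, of which 8256 carried only an Ensembl identifier; 1029 of these were given a symbol from a table of gene names and the others were not named. A symbol that ends in a point and a digit is a duplicated symbol and was read as uncertain. Groups were taken from the genotype label.

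Nuclei with fewer than 200 detected genes were removed (1 wild type nucleus). Doublets, droplets that hold more than 1 nucleus, were scored in each library with Scrublet as implemented in scanpy 1.11.5. Its own threshold called 1 nucleus in each library and had not worked, so the nuclei with the highest scores were removed at an expected rate of 0.8% per 1000 nuclei, which took out 178 wild type and 293 knockout nuclei; this treatment was chosen after the data were seen. There remained 4536 wild type nuclei with 17128569 UMIs and 5761 knockout nuclei with 15125185 UMIs. UMIs were scaled to 10000 per nucleus and log transformed. The 2000 most variable genes, chosen within each library and without CFTR and the mitochondrial transcripts, gave 30 principal components and a graph of 15 neighbours, which was clustered without integration by the Leiden method at resolution 1 (scanpy 1.11.5, python-igraph 0.11.9, Python 3.11.15).

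Clusters were named from marker lists of 22 cell types fixed before the data were examined. A marker counted for a cluster when its level in CPM, with 20 CPM added, was at least 1 log2 unit above the median of the other clusters, at least 5% of the nuclei had a UMI of it, and its level reached 50% of the highest level in any deep cluster. A name needed 3 such markers, more than any other type, and a median depth of at least 0.333 of that of the nuclei's own library. This score was set after the clusters were seen and several versions of it were tried, so the shares of classes depend on it. Clusters 0, 12 and 17 stayed unnamed. A class was compared by name only if none of its clusters had more markers of another type than of its own among its top 10 genes by fold. The ranking behind those top genes was at 1 point changed from the median to the mean of the other clusters after the precursor class had failed, which made it pass. That change was withdrawn as a choice, and a class now has to pass with both rankings. The globose basal or precursor class and the respiratory secretory class did not, and are given as cluster 13 and cluster 14. Names are written with "-like", since no annotation by the authors was used here.

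With 1 library per genotype there was no test, and the differences have no replicate check: they compare these libraries, not the genotypes. UMIs were summed over nuclei and given as CPM, a gene's UMIs over all UMIs of the nuclei multiplied by 1e6, with exact Poisson 95% intervals, shares of nuclei with exact Clopper-Pearson 95% intervals, ratios of CPM with the exact conditional binomial interval and ratios of shares with the log-normal interval. All intervals cover counting error only. Log2 ratios are knockout over wild type. A gene at 0 in a library was set to a floor of 3 counts for ranking and for list medians, and the limit given for a share of 0 is 3 nuclei of the total, which limits nuclei with a UMI and not nuclei that express the gene. Gene ratios were computed over all nuclei and within the 7 classes with at least 100 nuclei in both libraries. For 19 gene lists the median log2 ratio of members with at least 20 UMIs was set against 10000 random lists of the same size matched on mean expression, and described as outside when it left the central 95%. Single values of 2 list members are not reported here; both stay in the list medians and in the counts of values. The lists were proliferation core, S phase, neuronal differentiation factors, olfactory transduction and cilia, axon growth and guidance, basal cell adhesion and keratin, Notch pathway, Wnt pathway, anion and fluid transport, xenobiotic metabolism, mucus and secreted defence, inflammatory, interferon response, immediate early and heat shock, unfolded protein and oxidative stress, apoptosis, extracellular matrix, mitochondrial transcripts and Y-linked genes. A nucleus was called proliferating when UMIs of at least 2 genes of the proliferation core list remained after thinning it to 1000 UMIs at random; shallower nuclei were left out (378 wild type, 1325 knockout).

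The design, lists, markers, alternatives and the rule for named genes were fixed before the data were examined. The rule took CFTR; the 8 highest and 8 lowest ratios over all nuclei among genes with at least 200 UMIs; the 4 highest and 4 lowest in the mature, immature, precursor, horizontal basal and sustentacular classes among genes with at least 100 UMIs; from each list outside its random range, the 2 members with the most UMIs and the 2 with the largest ratio in its direction; and the Y-linked and mitochondrial transcripts. Because some of the highest genes within classes, such as BPIFA1, were higher in every class of the knockout library, a further rule was added after the data were seen, which took the 4 highest and 4 lowest among genes whose level in the class was at least 3 times the median of the other classes of that library. Genes among the top 10 of a cluster are not given as differences within that cluster's class, except CFTR, and except LAMA3 and TP63 where turned values are listed.

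Alternatives fixed beforehand were lower and higher cluster resolution (0.5 and 2), integration by reciprocal PCA (Seurat 5.3.0, R 4.3.3), each library clustered on its own, each nucleus named by its own marker score, doublets kept, a minimum of 500 genes per nucleus, TMM factors (edgeR 4.0.16) and median of ratios size factors (DESeq2 1.42.0) applied to the deposited counts summed per library, a mean over nuclei of per-nucleus CPM, list minimums of 5 and 100 UMIs, class means combined with the same weights in both libraries, and proliferating nuclei with at least 1 or 3 genes, without thinning or thinned to 500 UMIs. The term equal class weights stands for these same weights in both libraries, and large classes still count for more. Each class or unnamed cluster with at least 20 nuclei in both libraries was weighted by its mean share of their UMIs, and smaller ones were left out. Added after the data were seen were nuclei of at least 1000 UMIs only, thinning all nuclei to 1000 UMIs before clustering, clustering without the proliferation core and S phase genes, CFTR shares after thinning, leaving out the nuclei of the higher resolution's cluster with the highest median doublet score (114 wild type and 6 knockout nuclei), and the CFTR level with size factors, as a mean over nuclei, with 500 genes per nucleus and with equal class weights. For the explanation of the interferon list by cell composition, random lists drawn under equal class weights were also added after the first range had been seen. The intervals and list ranges were tested on simulated data drawn from the real gene means and library totals with 200 genes changed by 1 log2 unit. The counts were drawn with the Poisson error that the intervals assume, and the unchanged lists were random genes with independent error. The simulation therefore checks the calculation, and not false calls for lists whose genes change together. For all nuclei (11837 genes), 95.7% of the intervals held the true ratio, the changed genes recovered were 100%, and 7.25% of 400 unchanged lists fell outside their random range. For cluster 13 (3725 genes) these values were 95.6%, 96.5% and 4%.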

Results

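Nuclei of the olfactory mucosa, the lining of the nose that holds the olfactory sensory neurons, their basal stem cells and their sustentacular support cells, were compared between a wild type and a CFTR knockout newborn piglet. CFTR encodes the chloride and bicarbonate channel whose loss causes cystic fibrosis, and the title of the study names progenitor proliferation as its question. There was 1 library per genotype, so each value below stands for 1 animal and no difference was tested. After filtering, the wild type library held 4536 nuclei with a median of 2966 UMIs, and the knockout library 5761 nuclei with a median of 2093 UMIs. Below 1000 UMIs lay 378 wild type and 1325 knockout nuclei. Transcripts of the mitochondrial genome made up 2.83% of the wild type UMIs and 1.31% of the knockout UMIs.

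CFTR was lower in the knockout library, at 12.7 CPM (95% interval 11.0 to 14.6, 192 UMIs) against 88.9 CPM (84.5 to 93.5, 1523 UMIs), a ratio of 0.143 (0.122 to 0.166), with a log2 ratio of -2.81 and of -3.52 with equal class weights. In the wild type library its level was highest in microvillar or ionocyte-like nuclei, a rare type that expresses FOXI1, at 1512 CPM (1372 to 1662), against 123 CPM (80.9 to 179) in the knockout library. Cluster 12, in which the gland markers SOX9 and AQP5 were raised but which stayed unnamed, had 394 CFTR UMIs in 159 wild type nuclei and 3 in 169 knockout nuclei, which is 668 against 8.07 CPM, a ratio of CPM of 0.0121 (0.00248 to 0.0356). Sustentacular-like nuclei had 95.6 CPM against 10.1 CPM, horizontal basal-like nuclei 119 against 6.49 CPM and respiratory ciliated-like nuclei 339 against 29.3 CPM. Cluster 17, also with SOX9 and AQP5, had 94 and 1 UMIs, cluster 13 had 34 and 1, and cluster 14 had 465 and 21.7 CPM.

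CFTR was low in neurons. Mature neuron-like nuclei had 11.1 CPM in the wild type and 7.70 CPM in the knockout library, with a ratio of 0.693 (0.394 to 1.19), which does not separate the libraries. Immature neuron-like nuclei had 17.8 and 2.53 CPM. A CFTR UMI was found in 98.0% of the wild type and 20% of the knockout microvillar-like nuclei, and after thinning to 1000 UMIs in 88.2% (76.1% to 95.6%) of 51 and 12% (4.53% to 24.3%) of 50. Glia-like nuclei, which should lack it, had a CFTR UMI in 1 of 154 wild type and 0 of 184 knockout nuclei, which allows a share of nuclei with a UMI of up to 1.63%, and after thinning in none of 143 and 168. Their median depths were 2444.5 and 2029 UMIs, against 4022 and 2417 in microvillar-like nuclei. Cluster 18, the microvillar-like cluster, has CFTR among its top genes, but CFTR was not used for clustering. Which part of the transcript was counted is not given in the sources used here, so UMIs outside the disrupted part would not speak to the label.

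**Figure D1:**
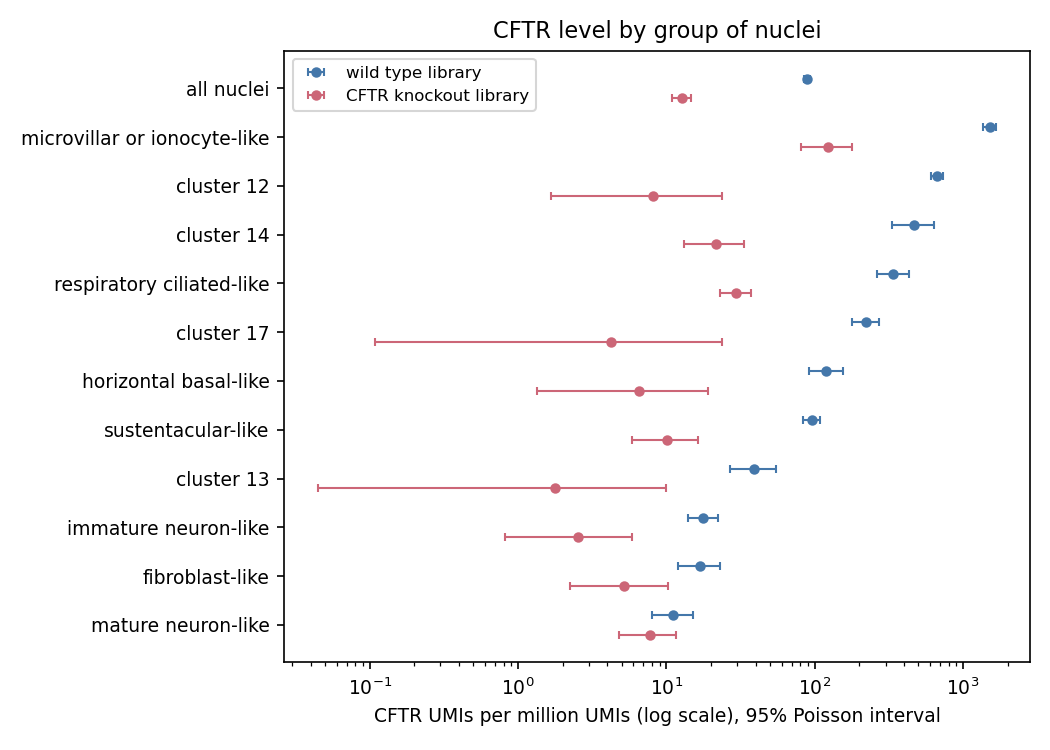
CFTR level in CPM, on a log axis, for all nuclei and for the classes or clusters shown, with a point and its 95% Poisson interval for the wild type library and for the CFTR knockout library (1 library each). The knockout point lies below the wild type point in each group drawn, from 123 against 1512 CPM in microvillar or ionocyte-like nuclei to 7.70 against 11.1 CPM in mature neuron-like nuclei, where the intervals overlap.

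Respiratory ciliated-like nuclei made up a larger part of the knockout library. These nuclei, with the axonemal dynein genes DNAH5 and DNAH9, were 8.23% (7.53% to 8.97%) of its nuclei against 0.705% (0.483% to 0.994%) in the wild type library, a log2 ratio of 3.54, which was 2.50 with each library clustered on its own and 1.38 with each nucleus named on its own. Cluster 14, with the secretory cell genes SCGB3A1, SPDEF, AGR2 and TFF3, was 4.46% against 0.485%. Cartilage or bone-like nuclei were 0.989% against 0.0882%, and endothelial-like nuclei 3.25% against 1.85%. Most olfactory types were a smaller part, with immature neuron-like nuclei at 9.56% against 19.3%, mature neuron-like nuclei at 15.9% against 19.6% (a log2 ratio of 0.062 with at least 500 genes per nucleus), sustentacular-like nuclei at 9.84% against 16.3% and cluster 13 at 1.98% against 3.92%. Horizontal basal-like nuclei were a larger part, at 4.08% against 2.89%, a direction that turned in other clusterings. The piece of mucosa dissected is not described beyond the tissue name, and these shares of all nuclei move with it.

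Within the neuronal lineage, mature neuron-like nuclei were 57.9% (55.4% to 60.4%) of the knockout nuclei against 45.8% (43.5% to 48.0%) of the wild type nuclei, a log2 ratio of 0.34. Immature neuron-like nuclei, with the growth-associated gene GAP43 and with GNG8, were 34.9% against 45.1%. Cluster 13, with NEUROD1, HES6, TOP2A and EZH2, was 7.22% (5.99% to 8.60%) against 9.17% (7.92% to 10.5%), a log2 ratio of -0.35. The log2 ratio of the mature share was 0.13 with each library clustered on its own and 0.15 with each nucleus named on its own. Without a cluster of deep nuclei with the highest doublet score it was 0.28 (0.19 to 0.38). That of the immature share was -0.042 and -0.098 with each library clustered and each nucleus named on its own, with intervals that include 0. That of cluster 13 was -0.72 with each library clustered on its own and 0.0071 when all nuclei were thinned to 1000 UMIs before clustering. Different clusters held most of the mature class, cluster 5 with 687 of the 889 wild type nuclei and cluster 3 with 830 of the 915 knockout nuclei.

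Among olfactory epithelial nuclei, horizontal basal-like nuclei, named for the reserve stem cells marked by KRT5 and TP63, were 9.64% in the knockout and 4.57% in the wild type library, a log2 ratio of 1.08. That direction turned in 5 of the other clusterings, for example to -0.99 after integration and to -1.14 without proliferation genes, and the class held 39 to 42 knockout nuclei in 4 of them in place of 235. Without proliferation genes the respiratory secretory class rose to 417 knockout nuclei, from 257. With at least 500 genes per nucleus it held 424, with TP63 among its top genes. Some horizontal basal-like nuclei of the knockout library may therefore be respiratory, which was not traced. Sustentacular-like nuclei were 23.3% against 25.8%, with cluster 4 holding 586 of the 740 wild type and cluster 8 holding 323 of the 567 knockout nuclei, and the log2 ratio was 0.30 with each nucleus named on its own. Microvillar or ionocyte-like nuclei were 2.26% against 1.78%, with overlapping intervals. Glia-like nuclei were 3.19% against 3.40% of all nuclei, macrophage-like nuclei 1.65% against 1.81%, pericyte-like nuclei 0.937% against 0.728% and fibroblast-like nuclei 14.3% against 17.7%, a direction that turned to a log2 ratio of 0.12 at lower resolution. Of the unnamed clusters, cluster 0, of shallow nuclei with a median of 546 UMIs, was 16.4% of the knockout and 4.83% of the wild type nuclei, cluster 12 was 2.93% and 3.51%, and cluster 17 was 1.39% and 1.74%. By markers cluster 0 scored highest as mature neuron, with CNGA2, GNG13, STOML3 and S100A5, but was too shallow for a name. Another type had 3 markers there, and BPIFA1, COL1A2, COL1A1 and TFF3 were among its top 10 genes. At higher resolution shallow nuclei fell into an unnamed cluster of 27 wild type and 910 knockout nuclei and another of 194 and 32. In the former, mature neuron and another type had 3 markers each, so the type of these nuclei stays open. The nuclei of cluster 0 count in the total for shares of all nuclei and not in any named class, which lowers the other knockout shares more.

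**Figure D2:**
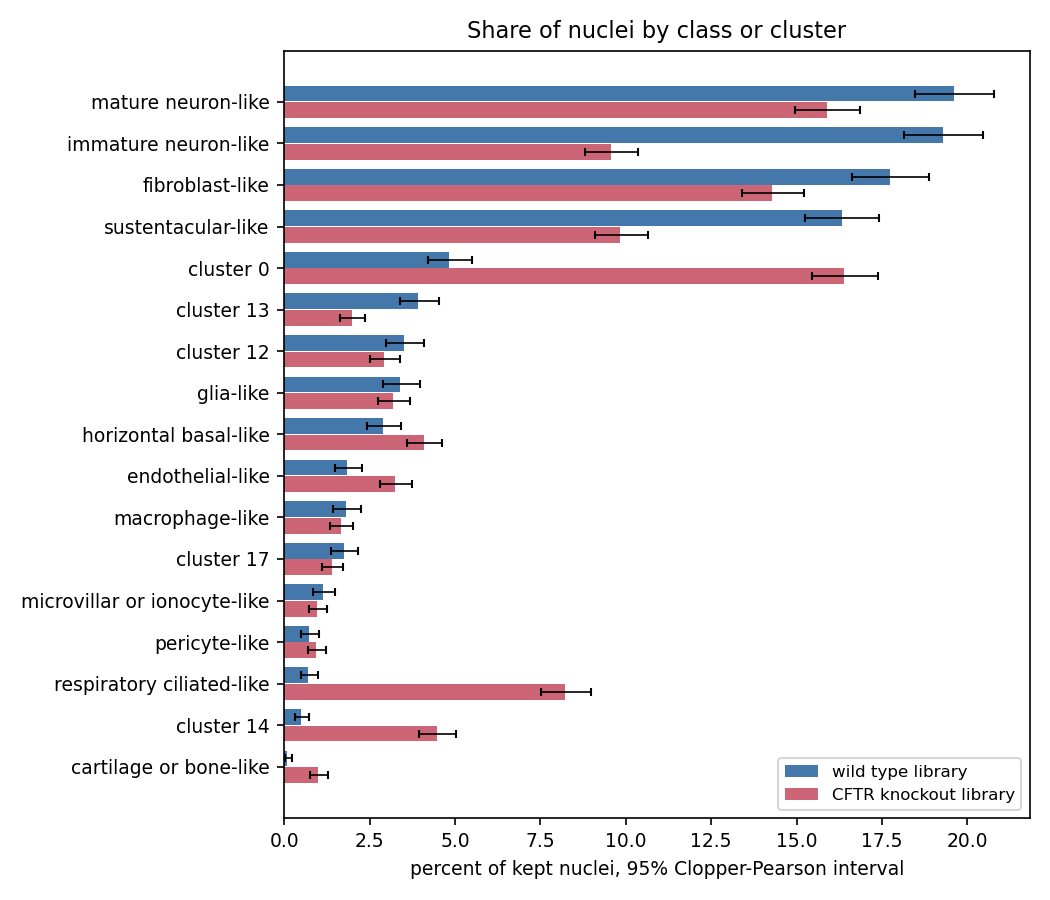
Percent of all kept nuclei (horizontal axis, from 0) in each named class or unnamed cluster, with 95% Clopper-Pearson intervals, for the wild type and the CFTR knockout library (1 library each). Immature neuron-like nuclei stand at 19.3% and 9.56%, and respiratory ciliated-like nuclei at 0.705% and 8.23%.

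After thinning, the share of proliferating nuclei did not differ between the libraries beyond counting error, over all nuclei or in cluster 13. Over all nuclei it was 5.23% (4.59% to 5.93%, 232 of 4436) in the knockout and 5.92% (5.22% to 6.68%, 246 of 4158) in the wild type library. Without thinning, where deeper nuclei pass more often, it was 15.8% and 22.1%. In cluster 13 it was 62.5% (52.9% to 71.5%, 70 of 112) against 58.4% (50.7% to 65.8%, 101 of 173), and without thinning 78.9% and 71.9%. Because proliferation genes such as TOP2A and DIAPH3 help to define that cluster, it was also found with the proliferation core and S phase genes left out of clustering. Its naming still drew on a marker list with MKI67, TOP2A and EZH2, so that dependence was reduced and not removed. Its proliferating share was then 50.4% (41.1% to 59.7%) in the knockout and 56.1% (48.4% to 63.7%) in the wild type library. In horizontal basal-like nuclei the shares were 3.38% (7 of 207) and 7.14% (9 of 126), with overlapping intervals, and without thinning 11.9% and 20.6%. Mature neuron-like nuclei, which do not divide, gave a background of 1.25% and 1.85% (10.3% and 18.6% without thinning), at median depths of 2856 and 3768 UMIs, against 3905 and 4058.5 UMIs in cluster 13.

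The nuclei called proliferating were spread differently over the cell types. Cluster 13 held 41.1% (34.8% to 47.5%) of them in the wild type and 30.2% (24.3% to 36.5%) in the knockout library, while respiratory ciliated-like nuclei, of which the knockout library had more, held 2.44% and 15.9%. Within ciliated-like nuclei the share called proliferating was 7.89% (5.62% to 10.7%, 37 of 469) in the knockout library. In the wild type library it was 18.8% (7.21% to 36.4%, 6 of 32). These intervals overlap, though that of the log2 ratio of -1.25 (-2.38 to -0.12) was all negative. Both shares lay above those of mature neuron-like nuclei. Whether these ciliated-like nuclei divide was not tested, and the shares over all nuclei include them. If they do not divide, the background of the call differs between cell types. That of mature neuron-like nuclei would then be too low for some of them, and low shares in other classes need not be dividing nuclei. The share was 4.83% in wild type and 3.39% in knockout fibroblast-like nuclei, 4.14% and 2.94% in sustentacular-like nuclei and 2.34% and 2.25% in immature neuron-like nuclei, each with overlapping intervals. Without thinning these were 17.3% and 8.87%, 19.7% and 13.2%, and 25.0% and 18.1%. With 1 proliferation gene as the threshold the order over all nuclei turned, with a log2 ratio of 0.078, against -0.18 with 2 genes.

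**Figure D3:**
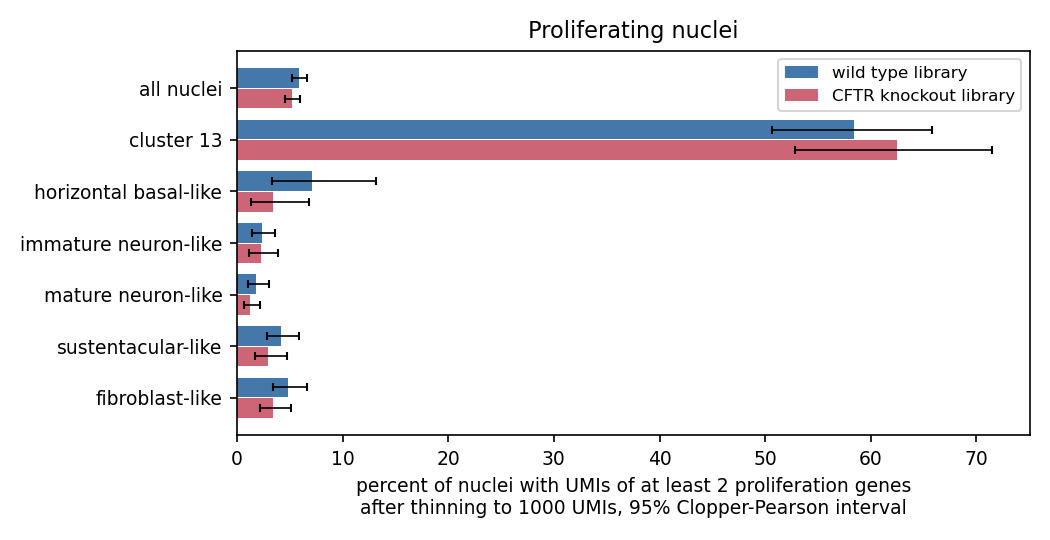
Percent of nuclei (horizontal axis, from 0) with UMIs of at least 2 proliferation core genes after thinning to 1000 UMIs, with 95% Clopper-Pearson intervals, over all nuclei and in 6 groups of nuclei, in the wild type and the CFTR knockout library (1 library each). Cluster 13 stands at 58.4% and 62.5%, and the other groups drawn at 7.14% or below.

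Over all nuclei, the lists of neuronal genes were lower in the knockout library, and those of mucus and secreted defence and of the interferon response were higher. The neuronal differentiation factors had a median log2 ratio of -0.65 (15 of 16 below 0, random range -0.21 to 0.20), with NEUROD1 at -1.32, INSM1 at -1.20, EBF1 at -0.63 and EBF2 at -0.45. Axon growth and guidance genes had -0.56 (22 of 25 below 0, -0.17 to 0.14), with the adhesion gene NCAM2 at -1.88, CNTN4 at -0.91, NCAM1 at -0.32 and the semaphorin receptor NRP2 at -0.92. Olfactory transduction genes had -0.36 (15 of 18 below 0, -0.18 to 0.22), with the odorant receptor chaperones RTP1 at -0.59 and RTP2 at -0.67, while the most abundant members PDE1C and RIC8B were at -0.12 and -0.29. The share of neurons was also smaller. With equal class weights the medians were -0.13 (random range -0.11 to 0.19), -0.25 (-0.07 to 0.15) and -0.15 (-0.10 to 0.18), nearer to 0 but still below their ranges, while EBF2, NCAM1 and PDE1C turned to 0.093, 0.19 and 0.14.

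Mucus and secreted defence genes had a median log2 ratio of 1.77 (11 of 12 above 0, random range -0.22 to 0.37), with the secretory proteins BPIFA1 at 4.42, SCGB3A1 at 5.81 and WFDC2 at 1.82, beside the larger share of cluster 14. All 21 measured interferon response genes were above 0, with a median of 0.99 (-0.10 to 0.34). Among them were the antiviral genes MX2 at 2.63 and IFIT1 at 1.92, and IFI44L at 0.55. MX2 is also among the top genes of cluster 14, so its ratio over all nuclei moves with the larger share of that cluster. Apoptosis genes had 0.34 (12 of 15 above 0, -0.14 to 0.33), with CASP8 at 1.85, APAF1 at 0.54, MDM2 at 0.41 and CDKN1A at 3.18 (1.46 to 5.55), the last with 24 against 3 UMIs. Mitochondrial transcripts had -1.24 (12 of 13 below 0, -0.48 to 0.02), from ND3 at -1.89 to ND5 at -0.66, while ND6 was at 0.41. With equal class weights their median was -1.86, with all 13 below 0. The libraries are of nuclei, and where these transcripts came from was not traced. Their ratios, over all nuclei or within classes, are therefore not read as lower mitochondrial expression in cells. At higher resolution their median percent of UMIs was 13.976 in an unnamed cluster of 194 wild type and 32 knockout nuclei. It was 5.19 in a mature neuron-like cluster of 223 and 23, and 3.11 in an unnamed cluster of 27 and 910.

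The proliferation core list had a median of -0.10 (14 of 23 below 0, random range -0.09 to 0.30), or -0.17 without the cluster of the highest doublet score, with the kinetochore gene NDC80 at -0.66 and KIF15 at -0.55, while its most abundant members NUSAP1 and SMC4 were at 0.30 and 0.16, the latter at -0.0018 with equal class weights. S phase genes had -0.13 (22 of 37 below 0, -0.04 to 0.30), with thymidylate synthase TYMS at -1.09, ATAD2 at -0.88 and NASP at 0.38. Extracellular matrix genes had -0.07 (14 of 21 below 0, -0.07 to 0.27), with COL3A1 at -0.55 and LAMB1 at -0.54, while COL1A1 at -0.38 and COL1A2 at -0.10 turned above 0 when nuclei were weighted equally. With equal class weights the proliferation core, S phase and apoptosis medians lay inside their random ranges, at -0.0018, 0.011 and 0.27.

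The other lists lay inside their random ranges over all nuclei. With equal class weights, however, Notch pathway genes at -0.16 (random range -0.13 to 0.25) and xenobiotic metabolism genes at -0.074 (-0.072 to 0.26) fell below theirs. Basal cell adhesion and keratin genes had a median of -0.06 (8 of 14 below 0), Notch pathway genes -0.15 (10 of 16 below 0), and Wnt pathway genes 0.18 (12 of 17 above 0). Anion and fluid transport genes had -0.07 (14 of 25 below 0). Xenobiotic metabolism genes had 0.10 (12 of 21 above 0), inflammatory genes 0.08 (12 of 22 above 0), immediate early and heat shock genes 0.24 (14 of 20 above 0), and unfolded protein and oxidative stress genes 0.21 (16 of 20 above 0). Y-linked genes were too sparse for a median, with EIF1AY at 9 UMIs in both libraries and KDM5D at 5 wild type and 3 knockout UMIs. All genes together had a median of 0.10 on the log2 scale. Size factors in place of total UMIs lower every ratio over all nuclei by 0.11 (TMM by 0.09). Positive medians near that size therefore have no firm sign, while negative medians move further from 0.

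**Figure D4:**
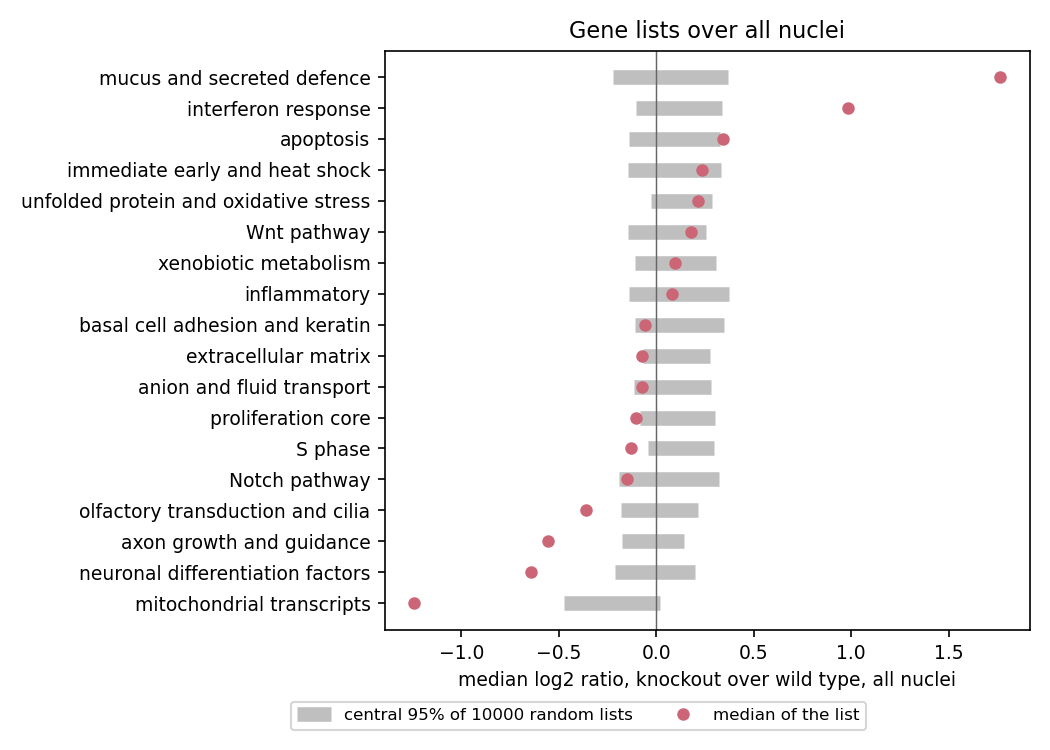
Median log2 ratio, knockout over wild type, of each gene list over all nuclei (points), with the central 95% of 10000 random lists matched on expression (grey bars). Mucus and secreted defence stands at 1.77 and interferon response at 0.99, above their bars, and mitochondrial transcripts at -1.24, below.

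Of single genes over all nuclei, those with the highest ratios included several with few wild type UMIs. SCGB3A1 had 248 against 5 UMIs, PTI 398 against 9 (log2 ratio 5.65), LY6D 940 against 32 (5.06), and TBATA and C2orf70 had log2 ratios of 4.64 and 4.56. Next came the tryptophan-degrading enzyme IDO1 with 390 against 20 UMIs (4.46), BPIFA1 with 11504 against 609 and WDR38 with a log2 ratio of 4.33. The lowest were the matrix metalloproteinase MMP3 with 78 against 933 UMIs (-3.40), DPYS (-2.83), CFTR (-2.81), the cytochrome P450 gene CYP2F1 with 712 against 3957 UMIs (-2.30), MATN4 (-2.29), the vitamin D-degrading enzyme CYP24A1 (-2.16), the deiodinase DIO2 (-2.14) and ND3 (-1.89). CYP2F1 and CYP24A1 lead clusters 4 and 9, of which cluster 4 was larger in the wild type library.

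Within classes, BPIFA1 was higher in each class of the knockout library, at 343 to 786 CPM in the 7 classes compared. In mature neuron-like nuclei, of which cluster 5 held 77.3% in the wild type and 9.29% in the knockout library and cluster 3 the others, BPIFA1 had 1155 against 23 UMIs. ODF3B had a log2 ratio of 5.37, TMEM212 5.19 and SERPINB11 4.90. TMEM212 was also higher in immature neuron-like (4.34) and sustentacular-like nuclei (4.13), so its ratio is not particular to mature neurons. Which cells these transcripts came from was not traced. The lowest were the mitochondrial transcripts ND3 (-2.66), ATP8 (-2.32), ND2 (-2.12) and ND4 (-2.10), whose source was not traced either. Among genes that mature neurons themselves express, FAM19A4 was at 3.25, the netrin receptor DCC at 2.66 (637 against 133 UMIs), SNTG1 at 2.32 and VWC2 at 2.09. The potassium channel KCNH5 was at -1.97, NCAM2 at -1.87 (654 against 3161 UMIs), PCSK1 at -1.83 and GALNT13 at -1.77. Within the clusters NCAM2 was lower by less, at 185 against 375 CPM in cluster 3 and 504 against 913 CPM in cluster 5. Below its random range in this class lay axon growth and guidance (-0.28, 17 of 25 below 0), with NCAM1 at 0.10 and NRP2 at -1.23, which was at 50.7 against 49.6 CPM within cluster 3 and 112 against 153 CPM within cluster 5. Immediate early and heat shock genes (-0.40, 10 of 14 below 0) also lay below it, with NR4A1 at -1.54 and FOS at -1.27. Above it lay unfolded protein and oxidative stress (0.26, 13 of 20 above 0), with the most abundant, HERPUD1, at -0.03, the quinone reductase NQO1 at 1.45 and HMOX1 at 2.28. NQO1 was not higher within the clusters, at 208 against 257 CPM in cluster 3 and 25.5 against 34.9 CPM in cluster 5. Xenobiotic metabolism (0.65, 11 of 12 above 0) also lay above it, with ALDH1A1 at 2.61 and ABCC1 at 0.04. Interferon response genes (0.48, 10 of 16 above 0) lay above it too, with IFIT1 at 4.45 (2.48 to 7.55) but IFI44L at -0.88, as did extracellular matrix genes (0.71, 14 of 16 above 0), with the fibroblast gene COL1A1 at 1.81.

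In immature neuron-like nuclei, cluster 10 held 30.2% of the wild type and 17.8% of the knockout nuclei, and cluster 2 the others. At higher resolution an unnamed cluster of deep nuclei, with a median of 10706 UMIs and the highest median doublet score (0.104), held 114 wild type and 6 knockout nuclei, of which 80 and 6 belong to this class and 33 and 0 to the fibroblast-like class. The highest genes of the class were BPIFA1 (6.01), TCTEX1D4 (4.85), TMEM212 (4.34) and LGALS3 (3.64), and the lowest was the GABA receptor subunit GABRB2 with 4 against 117 UMIs (-3.74, and -4.39 without that cluster). CYP27A1 (-3.45), ST6GALNAC5 (-3.23), which leads the glia cluster, and FIGN (-2.79) came next, but without that cluster they were at -1.75 (-4.17 to 0.036), -0.55 (-1.71 to 0.51) and 0.39 (-1.27 to 1.98). Notch pathway genes had a median of -0.53 (all 11 below 0, random range -0.32 to 0.28), which was -0.17 without that cluster (5 of 7 below 0, -0.33 to 0.29), inside its range. Of their members, HEY2 at -2.31 and NOTCH2 at -1.77 were then at -0.029 and 0.87, while RBPJ was at -0.45 and -0.53. Xenobiotic metabolism genes had -0.26 (9 of 14 below 0), with FMO1 at -2.40 and POR at -0.32, but 0.65, -0.33 and 0.49 without that cluster. That median and POR were also above 0 as a mean over nuclei, at 0.16 and 0.28, and with doublets kept, both at 0.18. Among genes that immature neurons themselves express, GFRAL was at 2.21, TTC23L at 1.82, SNTG1 at 1.56 and PDZRN4 at 1.34. CRTAC1 was at -1.98, CDH7 at -1.89 and FAM229B at -1.59, and all of these kept their direction without that cluster.

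At higher resolution the precursor class held 128 wild type and 94 knockout nuclei. Another cluster there, of 54 and 21 nuclei, was named immature neuron and shared the top genes THSD7B, CEP152, NFASC and ATP8B4 with cluster 13. The libraries may therefore fill cluster 13 with different mixtures, which was not traced. In cluster 13, neuronal differentiation factors had a median log2 ratio of -0.45 (12 of 15 below 0, random range -0.23 to 0.20), with the transcription factors SOX11 at -1.83, SOX4 at -1.42 and EBF1 at -0.39. The proliferation core list had 0.27 (20 of 23 above 0, -0.10 to 0.21) there, but 0.029 (-0.09 to 0.22) in the cluster found without proliferation genes. Basal cell adhesion and keratin genes had 0.70 (7 of 8 above 0), with TP63 at 1.49 and LAMA3 at 0.95. Axon growth and guidance genes had -0.21 (13 of 21 below 0), with NRP2 at -1.47, EFNA5 at -0.64 and NCAM1 at 0.16, the last at -0.34 as a mean over nuclei. Apoptosis genes had -0.33 (counting interval -0.66 to 0.18, 5 of 8 below 0), with BAX at -0.87 but APAF1 at 0.73. The highest single genes were BPIFA1 (7.29, interval 5.42 to 10.35), TFF3 (2.91), LHFPL3 (2.43) and IFITM3 (2.08), and the lowest ND3 (-2.00), PRKCA (-1.85), CYP2A19 (-1.69) and ND2 (-1.56). Among genes that the cluster itself expresses, GLYATL3 was at 1.26, CHST8 at 1.17 and ITGBL1 at 1.01. The chemokine receptor CXCR4 was at -1.44, GDA at -1.42 and FAT3 at -1.40.

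In horizontal basal-like nuclei the membership changed with the clustering, and at higher resolution they fell into a cluster of 27 wild type and 199 knockout nuclei and another of 105 and 39. Their highest genes were TCTEX1D4 (5.20, interval 3.61 to 7.50), BPIFA1 (4.90), LGALS3 (3.87) and RBFOX1 (3.84). Among genes that the class itself expresses, FOXP2 (3.57), L3MBTL4 (3.39) and CP (3.15) followed. DACH1 (-3.12), CYP2F1 (-2.88) and ABCA13 (-2.70) were among the lowest, of which CYP2F1 and ABCA13 are among the top genes of sustentacular cluster 4 and were also lower in fibroblast-like nuclei (-2.44 and -3.35). Axon growth and guidance genes had a median of -0.98 (15 of 16 below 0) with ROBO1 at -1.95 and ROBO2 at -1.16, the latter at 0.29 with at least 500 genes per nucleus and 0.075 with doublets kept. Xenobiotic metabolism genes had -0.52 (6 of 11 below 0), with CYP1A2 at -2.22 (4 against 20 UMIs) and the most abundant, EPHX1, at -0.52, but ALDH1A1 at 2.07 (161 against 41 UMIs). Neuronal differentiation factors had -0.52 (10 of 11 below 0) with HES6 at -2.32, and basal cell adhesion genes -0.46 (11 of 13 below 0) with DSC3 at -2.90. Interferon genes had 0.96 (10 of 12 above 0), with MX1 at 3.06 and with MX2, a top gene of cluster 14, at 5.27 (2.70 to 10.61). That median became -0.60 with at least 500 genes per nucleus, where MX1 was at -0.17, and -0.25 with doublets kept.

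In sustentacular-like nuclei, of which cluster 4 held 79.2% in the wild type and 43.0% in the knockout library and cluster 8 the others, the highest genes were BPIFA1 (4.70), TMEM212 (4.13), TCTEX1D4 (3.89) and C5orf49 (3.45). The lowest were CFTR (-3.24), the synaptic vesicle gene SV2C (-3.22) and ND3 (-2.35). Inflammatory genes had a median of -0.34 (4 above and 5 below 0, counting interval -0.63 to 0.16, random range -0.24 to 0.49), with NFKBIA at 0.49, the cytokine IL6 at 2 against 63 UMIs (-4.45, interval -7.53 to -2.54) and the siderophore-binding protein LCN2 at 129 against 588 UMIs (-1.66). Xenobiotic metabolism genes had -0.31 (9 of 15 below 0), with FMO2 at -1.22 and CYP3A29 at -1.05, while POR was at 0.09. S phase genes had -0.27 (18 of 29 below 0), with ATAD2 at -1.05, TYMS at -2.47 and NASP at 0.20, but 0.066 at a minimum of 100 UMIs. Proliferation core genes had -0.32 (counting interval -0.46 to 0.15), with 8 above and 9 below 0, the most abundant, NUSAP1, at 0.09, and DIAPH3 at -1.67, which turned to 0.25 with doublets kept. Among genes that the class itself expresses, RBFOX1 was at 2.24, DOK5 at 1.78, the amino acid transporter SLC7A8 at 1.77 and the GABA receptor subunit GABRB1 at 1.76. ADAMTS3 was at -2.23.

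Glia-like nuclei had the largest interferon median of the classes, at 1.46 (12 of 12 above 0, random range -0.25 to 0.46), with HERC5 at 2.41 and the RNA sensor gene DDX58 at 2.20. Their mitochondrial median, at 0.10, lay inside its random range, while in the other classes it lay between -1.25 in fibroblast-like and -1.94 in mature neuron-like nuclei. Fibroblast-like nuclei were spread differently over clusters in the libraries, with cluster 7 holding 40.7% of the wild type and 19.7% of the knockout nuclei and, at higher resolution, a cluster of 256 and 8 and another of 65 and 323. They had a proliferation core median of -0.64 (20 of 22 below 0, -0.32 to 0.36), with BUB1 at -1.99 and NDC80 at -1.73, on 4 and 5 knockout UMIs. Of its abundant members, NUSAP1 was at -0.07 and ECT2 at -0.46, the last at 0.0060 as a mean over nuclei. They had an inflammatory median of -0.48 (9 of 12 below 0), with PTGS2 at -1.99, CCL2 at -1.44 and LCN2 at -0.46, the last at 0.052 as a mean over nuclei. Their interferon median was 0.71 (16 of 18 above 0), with ISG15 at 1.89. Their axon growth and guidance median was -0.50 (19 of 22 below 0), their neuronal differentiation median -0.33 (9 of 14 below 0) and their xenobiotic median -0.36 (11 of 17 below 0), with POR at -0.51. That xenobiotic median and POR turned to 0.26 and 0.49 with at least 500 genes per nucleus, 0.13 and 0.42 as a mean over nuclei, and 0.34 and 0.50 with doublets kept. Without the 33 wild type nuclei of the cluster with the high doublet score, the xenobiotic median was 0.28, POR 0.55, the neuronal differentiation median -0.28 (-0.29 to 0.38), the axon growth median -0.28, LCN2 -0.046 and the mitochondrial median -0.75, while the proliferation core median stayed at -0.68 and the interferon median at 0.76. Mucus and secreted defence genes had medians from 0.91 in sustentacular-like nuclei to 2.91 in cluster 13, beside the larger shares of ciliated-like nuclei and cluster 14 and the BPIFA1 seen in each knockout class. In immature neuron-like and sustentacular-like nuclei and in cluster 13 the interferon medians lay inside their random ranges, at 0.29, 0.14 and -0.16, but that of immature neuron-like nuclei was 0.51 (-0.25 to 0.44) without the nuclei of the high doublet score.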

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

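Alternatives without replicates show how values move with the processing and do not test them. CFTR was at -2.76 with doublets kept and -2.90 with TMM factors on the log2 scale. Among alternatives added after the data were seen it was at -2.92 with size factors, -2.81 as a mean over nuclei and with at least 500 genes per nucleus, -2.87 without the cluster of the highest doublet score and -3.52 with equal class weights. The log2 ratio of the mature share of the lineage stayed above 0 and that of the immature share below 0 under all alternatives run. The 95% interval included 0 for the immature share with each library clustered on its own, and for both shares with each nucleus named on its own. Of the alternatives fixed beforehand, 2099 values stayed within the counting interval of the main value, 456 moved outside it in the same or an uncalled direction and 46 turned. Of those added after the data were seen, namely these for CFTR, nuclei of at least 1000 UMIs only, thinning before clustering, clustering without proliferation genes and leaving out the cluster with the highest doublet score, 258 stayed, 53 moved and 9 turned. The cause was not tested for the values below, which are log2 ratios.

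Horizontal basal-like nuclei turned among olfactory epithelial and all nuclei to -1.08 and -1.76 at lower resolution, -0.99 and -1.66 after integration, -1.12 and -1.78 with doublets kept, -1.11 and -1.55 with at least 500 genes per nucleus and -1.14 and -1.82 without proliferation genes. Each nucleus named on its own gave 0.61 and -0.046, and thinning before clustering 0.70 among epithelial nuclei. Sustentacular-like nuclei among epithelial nuclei were at -0.0087 at lower resolution, -0.013 with doublets kept, -0.0049 without proliferation genes and 0.30 with each nucleus named on its own. Within the lineage, each library clustered on its own gave -0.72 for cluster 13, -0.042 for immature and 0.13 for mature neurons. Each nucleus named on its own gave -0.098 for immature and 0.15 for mature. Higher resolution gave -0.50 and 0.46. Integration gave 0.24 for mature, 500 genes -0.55 for immature, and thinning before clustering 0.0071 for cluster 13. Among all nuclei, the ciliated share was at 2.50 with each library on its own and 1.38 with each nucleus on its own, the fibroblast share at 0.12 at lower resolution and the mature share at 0.062 with 500 genes; among epithelial nuclei the mature share was at -0.16 with each nucleus on its own.

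The proliferating share of all nuclei was at 0.078 with at least 1 gene and -0.49 without thinning. The proliferation core median over all nuclei was -0.20 with TMM factors, -0.21 with size factors, -0.22 as a mean over nuclei and -0.17 without the cluster of the highest doublet score, and in cluster 13 it was 0.029 without proliferation genes in the clustering. S phase in sustentacular-like nuclei was 0.066 at a minimum of 100 UMIs.

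With at least 500 genes per nucleus, horizontal basal-like nuclei had an interferon median of -0.60, the cluster 9 genes LAMA3 at 0.74 and TP63 at 0.21, MX1 at -0.17 and ROBO2 at 0.29, and fibroblast-like nuclei a xenobiotic median of 0.26 and POR at 0.49. In the main clustering LAMA3 and TP63 were negative in horizontal basal-like nuclei. With doublets kept, horizontal basal-like nuclei had an interferon median of -0.25, LAMA3 at 0.63, ROBO2 at 0.075 and TP63 at 0.028, fibroblast-like nuclei a xenobiotic median of 0.34 and POR at 0.50, immature neuron-like nuclei 0.18 for both, and sustentacular-like nuclei DIAPH3 at 0.25. As a mean over nuclei, the xenobiotic median was 0.13 in fibroblast-like and 0.16 in immature neuron-like nuclei, POR 0.42 and 0.28, ECT2 0.0060 and LCN2 0.052 in fibroblast-like nuclei, NCAM1 -0.34 in cluster 13, and COL1A1 0.055 and COL1A2 0.33 over all nuclei. Without the cluster of the highest doublet score, immature neuron-like nuclei had a xenobiotic median of 0.65, FIGN at 0.39, NOTCH2 at 0.87 and POR at 0.49, and fibroblast-like nuclei a xenobiotic median of 0.28 and POR at 0.55. With equal class weights over all nuclei, COL1A2 was at 0.021, EBF2 at 0.093, NCAM1 at 0.19, PDE1C at 0.14 and SMC4 at -0.0018. Depth limits genes with few UMIs, such as CFTR in neurons, and classes of few nuclei, such as the 32 ciliated-like and 22 cluster 14 nuclei of the wild type library.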

Other observations

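Tests chosen only after the result was seen were those of sampled region, of cell composition and free RNA for the interferon genes, and of free RNA and of wild type nuclei over all cell types for CFTR; the 2 depth tests used settings added after the data were seen, and the genes of the next paragraph were looked up by cluster after their values were seen.

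The mature neurons fell into clusters that differ in genes known from rodents to mark different parts of the epithelium, NQO1 in dorsal neurons and NCAM2 and NRP2 in the others. Cluster 3, with most of the knockout neurons, had NQO1 at 208 CPM in the knockout and 257 CPM in the wild type library, while cluster 5, with most of the wild type neurons, had 25.5 and 34.9 CPM. NCAM2 was at 185 and 375 CPM in cluster 3 and at 504 and 913 CPM in cluster 5, and NRP2 at 50.7 and 49.6 CPM and at 112 and 153 CPM. NCAM2 was therefore lower in the knockout library within both clusters, and NQO1 differed far more between clusters than between libraries.

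The interferon genes summed to 1838 CPM in knockout and 795 CPM in wild type glia-like nuclei, and to 860 and 495 CPM in fibroblast-like nuclei. Sustentacular-like nuclei had a high level in both libraries, at 786 and 747 CPM, and mature neuron-like nuclei a low one, at 259 and 201 CPM.

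A larger mature share of the neuronal lineage in the knockout library was not removed by depth: its log2 ratio was 0.34 (0.24 to 0.43) in nuclei of at least 1000 UMIs, a filter that left out only 2.90% of the lineage, and 0.25 (0.16 to 0.33) when all nuclei were thinned to 1000 UMIs before clustering. The place of the cluster borders stays open as an explanation, because without clusters the immature markers (median -0.57) and mature markers (-0.53) were lower by a like amount, with a difference of -0.041 (-0.38 to 0.13). The sampled region cannot be told apart from the genotype, since the ciliated share differed by a log2 ratio of 3.54 (2.50 with each library clustered and 1.38 with each nucleus named on its own) between the only libraries of each genotype. An effect of the genotype was not tested.

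Higher interferon response genes in the knockout library were not accounted for by the shares of the classes alone, since with equal class weights the median was 0.48, above the random range of -0.10 to 0.34 over all nuclei and of -0.08 to 0.27 under the same weights, though below the 0.99 without them. The values by class also argue against free RNA, provided that it spreads over classes about as BPIFA1 did, which varied by a factor of 2.29; free RNA itself was not measured. Glia-like nuclei gained 1043 CPM (887 to 1199), while immature neuron-like nuclei gained 41.1 CPM (upper bound 65.8), or 71.4 CPM (upper bound 96.0) without the cluster of the highest doublet score. Composition within classes stays open, because the libraries fill some classes with different clusters, which the class weights do not even out. An interferon response of the individual animal, for example to an infection, and an effect of the genotype also stay open. None of these was tested, with 1 animal per genotype.

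CFTR UMIs left in the knockout library were not spread over cell types as BPIFA1 was, which stands in for free RNA that was not measured, with 123 CPM (80.9 to 179) in microvillar-like nuclei against 5.14 CPM (3.58 to 7.15) in neurons, fibroblast-like and glia-like nuclei together. The largest part of the 192 UMIs, 37.5%, lay in respiratory ciliated-like nuclei, which held 16.2% of all knockout UMIs. Microvillar-like nuclei held 14.1% of the 192 and cluster 14 held 10.4%. Barcodes found in both libraries held 0% of the 192 UMIs. A few wild type nuclei in the library may account for part of the microvillar signal, since the highest knockout nucleus had 1.82 CFTR UMIs per 1000 UMIs against a wild type median of 1.61, and 2 of the 55 nuclei reached that median, on at most 4 UMIs each. Wild type nuclei as the source over all cell types would give a like knockout over wild type ratio of CFTR UMIs in each type. That ratio was 8.30 times (2.56 to 42.8) as high in microvillar-like nuclei (27 against 427 UMIs) as in cluster 12 (3 against 394 UMIs). The value goes against this source but does not settle it. Its interval takes UMIs as independent, though the knockout UMIs lay in only 11 microvillar-like and 3 cluster 12 nuclei, and is too narrow. Transcripts of the disrupted allele stay open and were not tested.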
